A study of Mus musculus with 15 samples.

How the data were processed

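Bulk RNA of frozen mouse forebrain was measured in 15 libraries, 3 in each of 5 groups. Per the labels' protocols, RNA was extracted with a kit for lipid-rich tissue, cDNA was made with a SMARTer Ultra Low kit, and libraries were sequenced on a NovaSeq-6000 with paired reads of 150 bases. The authors deposited a table with raw counts per gene and, for every library, the same counts scaled to a common total (CPM). Per the submitters' processing notes, DRAGEN, DESeq2 and the genome build mm10 were used; their versions, their roles, the annotation and the strand setting are not given in the sources used here. The deposited CPM equalled each count divided by its library total, to within rounding, so the counts carry no other normalization, and the tests used the counts.

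The table held 55774 rows for 55487 Ensembl gene identifiers. Rows that repeated an identifier held identical counts, and 287 of them were removed. Of the identifiers, 55227 were found in the GENCODE mouse release 21 annotation of mm10, from which positions were taken. Total counts per library ran from 19249641 to 54801136. Among counts of 1 to 4, 70.6% to 74.7% were even in each library, as if both mates of a pair were often counted; a count is then worth less than 1 independent fragment, and the spread between libraries, not counting error, set every test. The kit does not mark strand, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies, such as Lyz1 and Lyz2, the haemoglobin genes and the H2 genes, are uncertain. Floors cover counting error only.

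Libraries were grouped by the library name in their description. The libraries called PLX3X_CD30 there are titled only as PLX treated and those called PLX3X_CD0 as PLX 3x treated, and the group called IR_BMT has library names that end with IR and titles that name IR-BMT. Replicate numbers came from the titles. All 15 libraries entered each fit, and no replicate pair had counts within sampling noise of each other.

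Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, which left 21780 genes, one model with a mean per group, robust quasi-likelihood dispersions (biological coefficient of variation 12.1%) and two-sided quasi-likelihood F-tests of 9 comparisons, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error was the log2 fold change over the root of F. Gene lists were tested with camera in limma 3.58.1, a competitive test with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison, and again with an estimated correlation. The 31 lists, with 398 genes, covered microglia-restricted genes, genes shared by microglia and other macrophages, brain-engrafted bone marrow-derived macrophages, border-associated macrophages, MHC class I and II, interferon response, disease-associated microglia, cytokines, reactive astrocytes, astrocyte markers, myelin, oligodendrocyte precursors, newly formed oligodendrocytes, proliferation, neurogenesis, neurons, immediate early genes, p53 targets, lymphocytes, neutrophils, erythrocytes, endothelium, pericytes, meningeal fibroblasts, choroid plexus, ependyma, striatal, thalamic and hypothalamic neurons as signs of dissection, and cholesterol synthesis. The lists, comparisons, tests, alternatives and the rule for naming genes were fixed before the data were examined; no gene stood in more than 1 list.

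The rule named, per comparison, the 10 genes with the largest rise and as many with the largest fall (5 where the reference was not NT) among genes past the threshold with an average log2 CPM of at least 1 whose 3 libraries in one group all lay above those of the other, a separation that chance gives in 10% of genes. It added up to 4 members with the smallest adjusted p of each list that was called or had a member past the threshold, and 9 fixed genes (Csf1r, P2ry12, Tmem119, Cx3cr1, Aif1, Ms4a7, Apoe, Gfap and Mbp). Some genes that the rule named are not reported here. Genes named outside it as the members behind a count of 5 or fewer were chosen after their values were seen. A gene without counts in a group was compared with a floor of 3 counts per library.

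Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), a fit on the 6 libraries compared, the replicate number as a block, leaving out each library in turn and, for overlaps, a change of at least 2-fold. A per-library loess offset (span 0.3) on the length and GC content of the longest annotated transcript, known for 99.9% of the genes tested, was added after seeing the data. Overlaps of calls against the same NT libraries were set beside independent lists and simulations of unchanged groups.

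The procedure was tested on simulated counts for PLX1X against NT, with 21335 genes tested. Each gene was drawn at its mean over all 15 libraries, and each library at its own total. Changed genes were taken from those with an average log2 CPM above 1, so the shares called do not describe lower genes. Of genes changed 1.25-fold, 40% were called in the right direction, and of those changed 1.5-, 2- and 4-fold 72%, 94% and 100%, while 10 of 21120 unchanged genes were called. A list raised 1.25-fold had adjusted p = 2.28e-12 with camera, and 0 of 30 unchanged lists were called. The simulated genes were independent of each other, so this cannot show how camera behaves for lists of correlated genes. All groups were drawn with the same spread per gene and without trends in length or GC content. The 10 calls thus do not give the rate of false calls in the real data. Of the 95 list calls in the real data, 77 did not pass with an estimated correlation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.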

Results

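RNA of frozen forebrain from wild-type mice was sequenced in 15 libraries, 3 in each of 5 groups. The groups were untreated brains (NT), brains that received what the labels call PLX 1x (PLX1X), 2 groups whose library names carry PLX3X followed by CD0 or CD30 (PLX3X_CD0 and PLX3X_CD30), and brains named IR-BMT (IR_BMT). The labels do not spell out PLX, CD0, CD30 or IR-BMT, and the PLX3X_CD30 libraries are titled only as PLX treated, so their place among the 3x libraries rests on the library names. The series title concerns macrophages that derive from monocytes and engraft in the brain, and each comparison asks what the treatment changed in the forebrain transcriptome. Total counts ran from 19249641 in NT replicate 1 to 54801136 in PLX3X_CD0 replicate 3, and 21780 genes were tested. Levels are TMM-normalised CPM, counts scaled to a common library total, given as mean ± SD over n = 3 libraries. Log2 fold changes carry the standard error (SE) of the edgeR quasi-likelihood fit, and p-values are Benjamini-Hochberg adjusted. Ranges of adjusted p over all alternatives include the fit without the filter on low counts. There the prior degrees of freedom were infinite for the median gene, so the spread of such a gene did not enter its test. A pass in that fit alone therefore carries little weight. Counts of list members are those past edgeR over all genes tested, followed, where it differs, by the count adjusted over the list alone. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

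In PLX1X brains, transcripts of microglia and other macrophages were far below their NT level. Csf1r, the receptor on which microglia depend for survival (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149, mm10), stood at 9.00 ± 4.52 CPM against 165 ± 17.4 in NT, a log2 fold change of -4.19 ± 0.39 (adjusted p = 6.55e-05). P2ry12, a purinergic receptor of resting microglia (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871), fell from 40.2 ± 2.19 to 2.02 ± 0.721 CPM, a change of -4.31 ± 0.23 (adjusted p = 3.10e-08). All 17 tested genes shared by microglia and other macrophages fell, with a median log2 fold change of -3.69. Of the microglia-restricted genes, 11 of 13 fell over all genes tested and 12 adjusted over the list alone (median -3.17).

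Other myeloid genes were lower as well. Of 10 genes of border-associated macrophages, which line vessels and meninges, 7 fell (8 adjusted over the list alone), among them the mannose receptor gene Mrc1 at -4.97 ± 0.46 (-5.69 without PLX1X replicate 2) and the transglutaminase gene F13a1 at -5.06 ± 0.33 (ENSMUSG00000039109, chromosome 13, 36867178 to 37050244). Lyz2, a lysozyme of myeloid cells (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321), fell from 14.0 ± 4.05 to 2.67 ± 0.228 CPM. Ms4a7, listed here among genes of brain-engrafted bone marrow-derived macrophages (ENSMUSG00000024672, chromosome 19, 11321039 to 11336146), had 0.573 ± 0.165 CPM in NT and no count in the 3 PLX1X libraries, so it was at least 8.77-fold lower at a floor of 3 counts per library. Trem2, a receptor of phagocytic microglia, changed by -3.42 ± 0.16, and of the disease-associated microglia list 6 of 17 members fell (7 adjusted over the list alone) and 1, Fabp5, rose. The microglia-restricted, shared and border-associated lists held with an estimated correlation (adjusted p = 0.000899, 0.00292 and 0.00922). The bone marrow-derived list, with 7 of 12 members lower (8 adjusted over the list alone) and 1, Emilin2, higher, had adjusted p = 0.0710 with an estimated correlation, and the disease-associated list adjusted p = 0.0710 with an estimated correlation. Of the interferon response list 7 of 27 members fell (14 adjusted over the list alone), such as Parp14 at -1.11 ± 0.24, with adjusted p = 0.000165 for the list and adjusted p = 0.553 with an estimated correlation. The interferon list did not pass without NT replicate 2 (adjusted p from 3.59e-08 to 0.553 over all alternatives).

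Genes of cholesterol synthesis were higher in PLX1X, 10 of 16 over all genes tested and 12 adjusted over the list alone. Fdft1, squalene synthase, rose by 0.49 ± 0.06. The list had adjusted p = 2.77e-08 with the preset correlation and adjusted p = 0.0710 with an estimated correlation. Synaptic vesicle genes Syp and Syt1 rose by 0.39 ± 0.05 and 0.43 ± 0.06, and 5 of 14 genes of the neuronal list rose (Syp, Syt1, Grin1, Syn1 and Slc17a7) while 1 fell, the scaffold gene Dlg4 at -0.26 ± 0.06 (adjusted p = 0.238 with an estimated correlation for the list). Mbp, myelin basic protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637), fell from 4531 ± 480.0 to 3399 ± 101 CPM. Gfap, the intermediate filament of astrocytes, was at 309.5 ± 26.5 against 221 ± 59.3 CPM and did not pass (adjusted p = 0.161, though it passed without the filter on low counts, adjusted p from 1.86e-10 to 0.362 over all alternatives). The list of astrocyte markers was called lower, with a median of -0.225 and 6 of 13 members past edgeR (adjusted p = 0.144 with an estimated correlation). Ciart, a gene under control of the circadian clock (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251), rose by 1.73 ± 0.15. In total 3939 genes passed, 2171 higher and 1768 lower, of which 27 and 641 changed at least 2-fold. With an offset for transcript length and GC content, chosen after seeing the data, the split was 1943 higher and 1973 lower. A fit on these 6 libraries alone called 2143 genes.

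**Figure D1:**
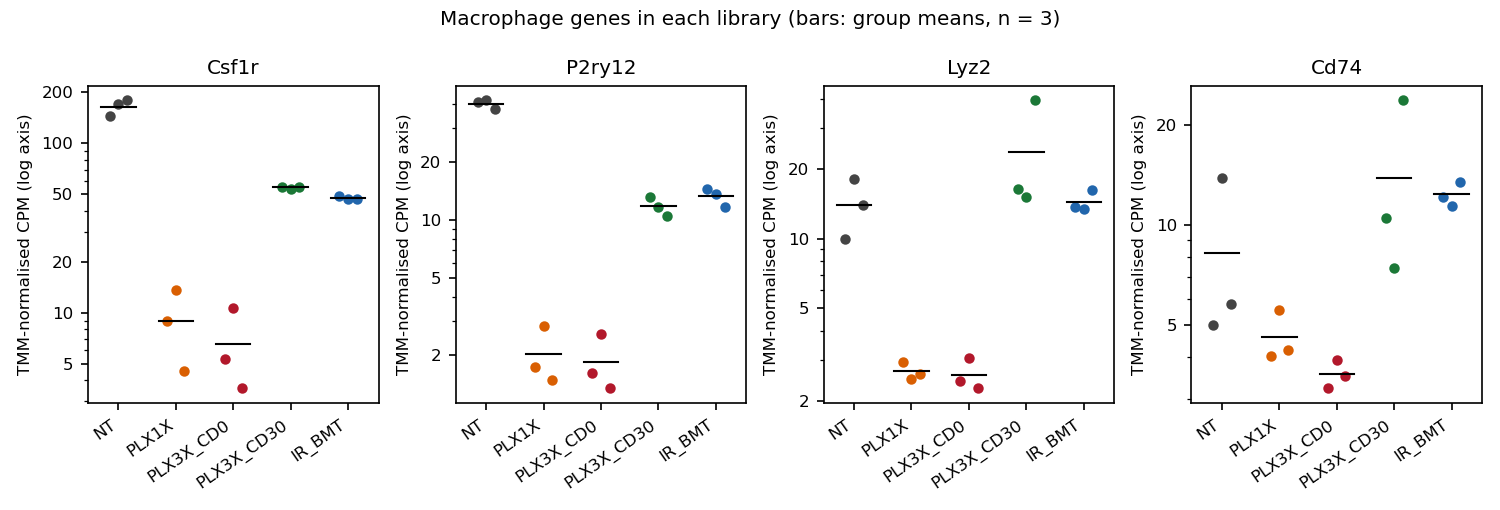
Levels of Csf1r, P2ry12, Lyz2 and Cd74 (4 panels) in each of the 15 libraries, in TMM-normalised CPM on a log axis, by group; points are libraries and horizontal bars are group means. Csf1r averaged 165 CPM in NT, 9.00 in PLX1X, 6.53 in PLX3X_CD0, 55.04 in PLX3X_CD30 and 47.5 in IR_BMT.

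PLX3X_CD0 brains were likewise far below NT in macrophage transcripts. Csf1r was at 6.53 ± 3.67 CPM, a log2 fold change of -4.66 ± 0.40 from NT (adjusted p = 2.02e-05), and the fractalkine receptor Cx3cr1 at 2.27 ± 0.979 against 75.8 ± 11.5 CPM (adjusted p = 5.73e-06). Siglech, a lectin of microglia (ENSMUSG00000051504, chromosome 7, 55768178 to 55778925), changed by -5.84 ± 0.30. All 17 shared macrophage genes fell (median -4.40), with 11 of 13 microglia-restricted genes (median -3.72) and 7 of 10 genes of border-associated macrophages (8 adjusted over the list alone). These 3 lists held with an estimated correlation (adjusted p = 0.00629, 0.000790 and 0.0232).

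Myelin genes were lower in PLX3X_CD0, with Mbp at 2867 ± 157 against 4531 ± 480.0 CPM. The myelin list had 6 of 14 members lower, adjusted p = 0.000306 and adjusted p = 0.380 with an estimated correlation. Of the 7 thalamic genes, which mark the dissection, 2 fell there too (Rora and Prkcd) and 4 adjusted over the list alone, adding Tcf7l2 and Rgs16, with the list not called (adjusted p = 0.0590) at a level -0.63 from NT. NT replicate 1 stood apart from the NT mean at 0.19 in the myelin list and 0.84 in the thalamic list, and the myelin median was -0.170 over all libraries and -0.0814 without that library (adjusted p = 0.0110). Rora did not pass without NT replicate 1, PLX3X_CD0 replicate 1 or PLX3X_CD0 replicate 2 or in a fit on these 6 libraries alone (adjusted p from 7.06e-07 to 0.135 over all alternatives), and Prkcd did not pass without NT replicate 1, PLX3X_CD0 replicate 1, PLX3X_CD0 replicate 2 or PLX3X_CD0 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 2.87e-89 to 0.131 over all alternatives), whose log2 fold change was -2.11 ± 0.61 and -1.19 without NT replicate 1. Bcas1, a marker of newly formed oligodendrocytes, changed by -1.08 ± 0.09, and 3 of 8 genes of that list fell (Bcas1, Enpp6 and Sirt2), 4 adjusted over the list alone, adding Gpr17, and adjusted p = 0.126 with an estimated correlation. The list did not pass without PLX3X_CD0 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 0.00253 to 0.126 over all alternatives). Of the astrocyte markers, 11 of 13 fell over all genes and 12 adjusted over the list alone, by a median of -0.31, with the glutamate transporter Slc1a2 at -0.44 ± 0.07 (adjusted p = 0.0850 with an estimated correlation). Lss, lanosterol synthase, rose by 0.60 ± 0.06, with 10 of 16 cholesterol genes higher over all genes and 11 adjusted over the list alone (adjusted p = 0.0685 with an estimated correlation). In total 4732 genes passed, 2657 higher and 2075 lower, but 2065 higher and 2244 lower with the length and GC offset. The fit on these 6 libraries alone called 2601.

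PLX1X vs NT and PLX3X_CD0 vs NT shared 2705 calls in the same direction, 1594 higher and 1111 lower, with 4 in opposite directions. The calls shared in the same direction were 1384 in fits on 2 groups at a time. Independent lists of these sizes would share 265 higher and 168.4 lower genes, and 20 simulations of unchanged groups against the same NT libraries shared at most 0, as unchanged groups gave too few calls to share any, so that number does not bear on the shared libraries. The covariance of the log2 fold changes across genes was 0.266, against a mean of 0.0516 in the simulations, and their correlation 0.753 against a mean of 0.522. The simulations gave all groups the same spread per gene. Chi-square per degree of freedom between replicates was 16.8 to 27.1 in NT and 5.91 to 10.5 in PLX1X. The simulated covariance from the shared controls may thus be too small. How much of the excess comes from the shared controls cannot be told, since 3 NT libraries are too few to split. With both changes at least 2-fold, 428 genes were shared.

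In PLX3X_CD30 brains, macrophage transcripts also lay below NT. P2ry12 was at 11.9 ± 1.38 CPM against 40.2 ± 2.19 in NT, a log2 fold change of -1.76 ± 0.19 (adjusted p = 0.000284), and Csf1r at 55.04 ± 1.10 CPM, a change of -1.59 ± 0.34 (adjusted p = 0.0232). Csf1r did not pass without PLX3X_CD30 replicate 1, PLX3X_CD30 replicate 2 or PLX3X_CD30 replicate 3 (adjusted p from 1.20e-89 to 0.0899 over all alternatives). Crybb1, a crystallin expressed by microglia (ENSMUSG00000029343, chromosome 5, 112255815 to 112269585), fell from 6.46 ± 0.949 to 1.00 ± 0.352 CPM, a change of -2.69 ± 0.25. Of the microglia-restricted genes 9 of 13 fell (10 adjusted over the list alone, median -1.37), and the list held (adjusted p = 0.0282 with an estimated correlation). Of the shared macrophage genes 6 of 17 fell over all genes and 16 adjusted over the list alone (adjusted p = 0.210 with an estimated correlation). The edgeR fit takes the spread of a gene from all 15 libraries. The log2 level of the shared list had an SD of 0.59 in PLX1X and 0.43 in PLX3X_CD0, against 0.06 in PLX3X_CD30 and 0.12 in NT. A lack of calls here thus does not show that shared genes, Csf1r among them, were unchanged.

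Lyz2 stood at 16.4, 15.1 and 39.6 CPM in the 3 PLX3X_CD30 libraries. Its reads can be shared by the related gene Lyz1, and its mean was 23.7 ± 13.8 against 14.0 ± 4.05 CPM (adjusted p = 0.226, though it passed without the filter on low counts, adjusted p from 2.92e-07 to 0.724 over all alternatives) and Ms4a7 at 0.594 ± 0.443 against 0.573 ± 0.165 CPM (adjusted p = 0.951), differences within the spread between replicates. The log2 fold change of Lyz2 was 0.74 ± 0.33 and 0.16 without PLX3X_CD30 replicate 3, and that of Ms4a7 0.09 ± 0.57 and -0.66 without PLX3X_CD30 replicate 3. Of the list of bone marrow-derived macrophages, 1 of 12 fell, the prostaglandin dehydrogenase gene Hpgd at -0.83 ± 0.23, and the list was not called (adjusted p = 0.556). Hpgd did not pass without NT replicate 1, NT replicate 3, PLX3X_CD30 replicate 1, PLX3X_CD30 replicate 2 or PLX3X_CD30 replicate 3 or with the length and GC offset (adjusted p from 0.00350 to 0.118 over all alternatives). In all, 2 of 14 myelin genes, 2 of 8 genes of newly formed oligodendrocytes and 6 of 14 neuronal genes passed edgeR. With an estimated correlation, adjusted p = 0.392 for the myelin and 0.186 for the neuronal list. Mbp changed by -0.40 ± 0.07 and Bcas1 by -0.56 ± 0.09, while Syp and Syt1 rose by 0.35 ± 0.05 and 0.41 ± 0.06. Signs of dissection moved with them: the thalamic list was called lower with a median of -0.53 (adjusted p = 0.0373, and adjusted p = 0.571 with an estimated correlation), and the striatal list with -0.28 (adjusted p = 0.0115, and adjusted p = 0.571 with an estimated correlation). None of their 7 and 9 members passed edgeR, with 2 at an unadjusted p under 0.05 and 0 past DESeq2 in the thalamic and 0 and 0 in the striatal list. The thalamic list did not pass without PLX3X_CD30 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 0.00132 to 0.894 over all alternatives), and without NT replicate 1 its median was 0.0393 (adjusted p = 0.894). The striatal list did not pass without PLX3X_CD30 replicate 3 (adjusted p from 2.91e-05 to 0.571 over all alternatives). NT replicate 1 lay at 0.84 from the NT mean in the thalamic and 0.19 in the myelin list, and without it Mbp changed by -0.32 (adjusted p = 0.00378) and Bcas1 by -0.39 (adjusted p = 0.00120). Of the oligodendrocyte precursor list 1 of 9 fell, Olig1 at -0.36 ± 0.07, with adjusted p = 0.0146 and adjusted p = 0.408 with an estimated correlation. Olig1 did not pass in a fit on these 6 libraries alone (adjusted p from 4.82e-05 to 0.0557 over all alternatives), and the precursor list did not pass without NT replicate 3 (adjusted p from 0.000882 to 0.408 over all alternatives). Fdft1 rose by 0.44 ± 0.06, with 7 of 16 cholesterol genes higher (adjusted p = 0.186 with an estimated correlation). In total 1432 genes passed, 1032 higher and 400 lower, or 873 higher and 560 lower with the length and GC offset and 1106 higher and 928 lower without the filter on low counts. The fit on these 6 libraries alone called 359 genes, 208 higher and 151 lower, and the count was 756 without PLX3X_CD30 replicate 1, 658 without PLX3X_CD30 replicate 2 and 608 without PLX3X_CD30 replicate 3.

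IR_BMT brains were also below NT in macrophage transcripts, and lower in myelin genes. Csf1r was at 47.5 ± 1.17 CPM, a log2 fold change of -1.80 ± 0.35 (adjusted p = 0.00277), and P2ry12 at 13.3 ± 1.43 CPM, a change of -1.59 ± 0.19 (adjusted p = 2.93e-05). Of the shared macrophage genes 10 of 17 fell (11 adjusted over the list alone, median -1.02) and of the microglia-restricted genes 8 of 13 (9 adjusted over the list alone, median -0.92). Mbp fell from 4531 ± 480.0 to 2917 ± 147 CPM and Bcas1 from 151 ± 26.3 to 69.1 ± 3.07 CPM, and 9 of 14 myelin genes fell over all genes and 10 adjusted over the list alone. With an estimated correlation, adjusted p = 0.667 for the shared, 0.497 for the microglia-restricted and 0.497 for the myelin list, and no list held. Of the 7 thalamic genes, which mark the dissection, 2 fell there too (Lef1 and Tcf7l2) and 1, Lef1, adjusted over the list alone, with the list not called (adjusted p = 0.0842) at a level -0.66 from NT. Lef1 did not pass without NT replicate 1 (adjusted p from 0.000330 to 0.0510 over all alternatives), and Tcf7l2 did not pass without IR_BMT replicate 1, IR_BMT replicate 2 or IR_BMT replicate 3, with the length and GC offset, or in a fit on these 6 libraries alone (adjusted p from 6.31e-27 to 0.214 over all alternatives). The change of Tcf7l2 was -1.18 ± 0.40 and -0.42 without NT replicate 1. NT replicate 1 stood apart in these lists, and the myelin median was -0.553 over all libraries and -0.460 without that library (adjusted p = 2.87e-07).

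Genes of dividing cells moved both ways. Mki67, a marker of proliferation (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), was at 0.446 ± 0.184 against 2.12 ± 0.928 CPM (adjusted p = 0.000167) and the topoisomerase Top2a changed by -1.39 ± 0.28, whereas the replication gene Mcm2 rose by 0.59 ± 0.13. Of the proliferation list 7 of 24 fell and 3 rose (Mcm2, Mcm5 and Pcna), and the list was not called (adjusted p = 0.108). Lyz2 was at 14.5 ± 1.54 CPM and Ms4a7 at 0.491 ± 0.194 CPM (adjusted p = 0.843), and 2 of 12 genes of the bone marrow-derived list passed edgeR. Slco1a4, a transporter of brain endothelium, changed by -0.48 ± 0.07, and 6 of 12 endothelial genes fell, though the list was not called (adjusted p = 0.125). Striatal neuron genes, a sign of dissection, were lower, 6 of 9 (7 adjusted over the list alone). The tachykinin precursor Tac1 was at -1.15 ± 0.25 and the phosphatase inhibitor Ppp1r1b at -0.81 ± 0.18. The list had adjusted p = 0.000164, and adjusted p = 0.667 with an estimated correlation. Its level was -0.75 from NT, with the IR_BMT libraries from -0.97 to -0.32. Dissection was not tested as a source of this change, of the neuronal change or of the lower myelin genes. The vesicular glutamate transporter gene Slc17a7 rose by 0.84 ± 0.09, with 7 of 14 neuronal genes higher (adjusted p = 0.497 with an estimated correlation). The cholesterol list was called higher, with a median of 0.231 and 9 of 16 members past edgeR (adjusted p = 0.512 with an estimated correlation). It was thus called higher in each treated group against the same NT libraries, and a low level in NT would also give this. In total 6658 genes passed, 3293 higher and 3365 lower, of which 5806 changed less than 2-fold. Across genes, which are not independent replicates, the log2 fold change followed GC content with a Spearman coefficient of 0.523.

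PLX3X_CD30 vs NT and IR_BMT vs NT shared 1153 calls in the same direction, 858 higher and 295 lower, with 4 in opposite directions. The calls shared in the same direction were 639 without PLX3X_CD30 replicate 1, 598 without PLX3X_CD30 replicate 2, 524 without PLX3X_CD30 replicate 3 and 320 in fits on 2 groups at a time. Independent lists of these sizes would share 156 higher and 61.8 lower genes, and 20 simulations of unchanged groups against the same NT libraries shared at most 0, as unchanged groups gave too few calls to share any, so that number does not bear on the shared libraries. The covariance of the log2 fold changes across genes was 0.143, against a mean of 0.0517 in the simulations, and their correlation 0.584 against a mean of 0.503. The simulations gave all groups the same spread per gene. Chi-square per degree of freedom between replicates was 16.8 to 27.1 in NT, 3.91 to 7.85 in PLX3X_CD30 and 5.01 to 12.7 in IR_BMT. The simulated covariance from the shared controls may thus be too small. How much of the excess comes from the shared controls cannot be told, since 3 NT libraries are too few to split. With both changes at least 2-fold, 54 genes were shared.

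Between PLX3X_CD0 and PLX1X, both low in macrophage transcripts, 1 of 13 microglia-restricted genes passed edgeR, against 2 with DESeq2. The gene past edgeR, Siglech, was at 0.332 ± 0.149 against 1.02 ± 0.462 CPM, a log2 fold change of -1.63 ± 0.33 (adjusted p = 0.0151). Csf1r was at 6.53 ± 3.67 against 9.00 ± 4.52 CPM (adjusted p = 0.637, though it passed without the filter on low counts, adjusted p from 1.60e-05 to 0.968 over all alternatives), and of 17 shared macrophage genes none passed over all genes tested with edgeR, with 3 at an unadjusted p under 0.05 and 1 past DESeq2, and 1, Ly86, fell adjusted over the list alone. Both lists were called lower, the microglia-restricted with a median of -0.28 (adjusted p = 0.0214, and adjusted p = 0.857 with an estimated correlation) and the shared with -0.61 (adjusted p = 0.000522, and adjusted p = 0.857 with an estimated correlation). The microglia-restricted list did not pass without PLX1X replicate 2, PLX3X_CD0 replicate 1 or PLX3X_CD0 replicate 3, with a stricter filter, or in a fit on these 6 libraries alone (adjusted p from 9.66e-08 to 0.857 over all alternatives), and the shared list did not pass without PLX1X replicate 2 (adjusted p from 4.44e-15 to 0.857 over all alternatives). Ciart was at 14.3 ± 0.565 against 39.6 ± 4.56 CPM, a change of -1.47 ± 0.14 (adjusted p = 6.67e-05). Egr1, an activity-dependent transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), was at 503 ± 53.5 against 896 ± 196 CPM, a change of -0.83 ± 0.16 (adjusted p = 0.0213).

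The immediate early list had 1 of 12 members lower over all genes, Egr1 (5 with DESeq2), and 6 adjusted over the list alone, with adjusted p = 1.51e-09 and adjusted p = 0.750 with an estimated correlation. None of the 24 proliferation genes passed with edgeR, with 3 at an unadjusted p under 0.05 and 0 past DESeq2, while their list was called lower (median -0.23, adjusted p = 0.00548, and adjusted p = 0.465 with an estimated correlation). Ttr, the main secreted protein of the choroid plexus, was at 498 ± 852 against 3.56 ± 0.675 CPM and did not pass (adjusted p = 0.197, though it passed without the filter on low counts, adjusted p from 0 (under the range of the software) to 0.893 over all alternatives), the 3 PLX3X_CD0 libraries holding 1481, 5.94 and 6.68 CPM, for a log2 fold change of 7.12 ± 2.49 and 0.82 without PLX3X_CD0 replicate 1. The choroid plexus list was called higher (adjusted p = 0.00660, and adjusted p = 0.857 with an estimated correlation) with none of 10 members past the edgeR test, with 6 at an unadjusted p under 0.05 and 0 past DESeq2, and without PLX3X_CD0 replicate 1 its median turned to -0.17. Fbn1, fibrillin, rose by 1.05 ± 0.19. In total 536 genes passed, 390 higher and 146 lower, whereas DESeq2 called 1066, 651 higher and 415 lower, a fit without the filter on low counts 1186, and the length and GC offset left 328, 149 higher and 179 lower. The count was 242 without PLX1X replicate 1, 150 without PLX1X replicate 2, 255 without PLX1X replicate 3, 231 without PLX3X_CD0 replicate 1, 289 without PLX3X_CD0 replicate 2 and 272 without PLX3X_CD0 replicate 3. Siglech did not pass without PLX1X replicate 1, PLX1X replicate 2, PLX3X_CD0 replicate 1 or PLX3X_CD0 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 1.74e-09 to 0.0766 over all alternatives). Egr1 did not pass without PLX1X replicate 2, PLX1X replicate 3, PLX3X_CD0 replicate 1 or PLX3X_CD0 replicate 2 or in a fit on these 6 libraries alone (adjusted p from 2.80e-29 to 0.101 over all alternatives).

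Macrophage transcripts were higher in PLX3X_CD30 than in PLX1X. F13a1 was at 3.59 ± 0.831 against 0.145 ± 0.0332 CPM, a log2 fold change of 4.61 ± 0.33 (adjusted p = 2.10e-07). P2ry12 was at 11.9 ± 1.38 against 2.02 ± 0.721 CPM (adjusted p = 2.68e-05) and Lyz2 at 23.7 ± 13.8 against 2.67 ± 0.228 CPM, a change of 3.14 ± 0.37 (adjusted p = 0.00146, with a log2 fold change of 2.55 without PLX3X_CD30 replicate 3). Of the shared macrophage genes 16 of 17 rose (17 adjusted over the list alone, median 2.60), of the microglia-restricted genes 9 of 13 (10 adjusted over the list alone), and of the border-associated genes 5 of 10 (F13a1, Mrc1, Stab1, Clec4n and Pf4), 7 adjusted over the list alone.

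Of the bone marrow-derived list 3 of 12 rose over all genes (Ms4a7, Lyz2 and Hpgd) and 6 adjusted over the list alone. Ms4a7 was at 0.594 ± 0.443 CPM with no count in PLX1X, at least 9.10-fold higher, or 5.39 without PLX3X_CD30 replicate 3. The microglia-restricted, shared, border-associated and bone marrow-derived lists held with an estimated correlation (adjusted p = 0.000670, 0.000670, 0.000670 and 0.0107). None of 8 MHC class II genes passed over all genes with edgeR, with 5 at an unadjusted p under 0.05 and 1 past DESeq2, and 3 (Cd74, H2-Eb1 and H2-Ab1) rose adjusted over the list alone. Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), was at 13.9 ± 8.70 against 4.59 ± 0.830 CPM (adjusted p = 0.148, though it passed without the filter on low counts and with DESeq2, adjusted p from 8.27e-25 to 0.397 over all alternatives), a log2 fold change of 1.60 ± 0.45 and 0.96 without PLX3X_CD30 replicate 3, and that list had adjusted p = 0.000439 and adjusted p = 0.204 with an estimated correlation. H2-T23 of the MHC class I list rose by 0.61 ± 0.12, 1 of 14 members and 4 adjusted over the list alone, adding H2-D1, B2m and H2-K1 (adjusted p = 3.80e-05 for the list, and adjusted p = 0.216 with an estimated correlation). The cytokine Tgfb1 rose by 1.43 ± 0.23, with 2 of 7 cytokine genes higher (Tgfb1 and Ccl12) and 4 adjusted over the list alone, adding Cxcl16 and Il1a (adjusted p = 0.139 with an estimated correlation). In total 263 genes passed, 235 higher, of them 134 at least 2-fold, and 28 lower. The fit on these 6 libraries alone called 814 (539 higher and 275 lower), DESeq2 553 (380 higher and 173 lower) and a fit without the filter on low counts 696 (492 higher and 204 lower). The count was 125 without PLX1X replicate 1, 127 without PLX3X_CD30 replicate 1, 172 without PLX3X_CD30 replicate 2 and 126 without PLX3X_CD30 replicate 3. Lyz2 did not pass in a fit on these 6 libraries alone (adjusted p from 4.81e-111 to 0.0703 over all alternatives). H2-T23 did not pass without PLX1X replicate 1, PLX1X replicate 3, PLX3X_CD30 replicate 1 or PLX3X_CD30 replicate 3 (adjusted p from 7.69e-07 to 0.0794 over all alternatives), and the cytokine list did not pass without the filter on low counts (adjusted p from 0.000139 to 0.139 over all alternatives), its median -0.15 without the filter against 0.92 reported.

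Macrophage transcripts were also higher in PLX3X_CD30 than in PLX3X_CD0. Siglech was at 7.31 ± 0.851 against 0.332 ± 0.149 CPM, a log2 fold change of 4.45 ± 0.30 (adjusted p = 3.69e-07). Cx3cr1 rose by 3.54 ± 0.37 and Lyz2 by 3.20 ± 0.37 (2.60 without PLX3X_CD30 replicate 3). All 17 shared macrophage genes rose (median 3.27, and 3.94 without PLX3X_CD0 replicate 2), with 10 of 13 microglia-restricted genes (11 adjusted over the list alone, median 1.77). Bcas1 rose by 0.52 ± 0.09, while the extracellular matrix genes Fbn1 and Lama5 changed by -0.96 ± 0.19 and -0.82 ± 0.14.

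The microglia-restricted, shared, border-associated and bone marrow-derived lists held with an estimated correlation (adjusted p = 0.000756, 0.00121, 0.00282 and 0.0130). Ighm, the heavy chain of immunoglobulin M, rose from 20.5 ± 4.89 to 38.9 ± 2.85 CPM. Lss changed by -0.34 ± 0.06. Cd74 was at 13.9 ± 8.70 against 3.55 ± 0.351 CPM (adjusted p = 0.0395), a change of 1.97 ± 0.46 and 1.33 without PLX3X_CD30 replicate 3. Cd74 did not pass without PLX3X_CD0 replicate 1, PLX3X_CD0 replicate 2, PLX3X_CD0 replicate 3, PLX3X_CD30 replicate 1 or PLX3X_CD30 replicate 3, with the length and GC offset, or in a fit on these 6 libraries alone (adjusted p from 4.04e-37 to 0.139 over all alternatives). In total 828 genes passed, 407 higher and 421 lower, against 484 and 227 with the length and GC offset, and a fit without the filter on low counts called 1395. The count was 550 without PLX3X_CD0 replicate 1, 453 without PLX3X_CD0 replicate 3, 384 without PLX3X_CD30 replicate 1, 419 without PLX3X_CD30 replicate 2 and 550 without PLX3X_CD30 replicate 3. Fbn1 did not pass without PLX3X_CD30 replicate 2 (adjusted p from 3.33e-07 to 0.0540 over all alternatives).

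**Figure D2:**
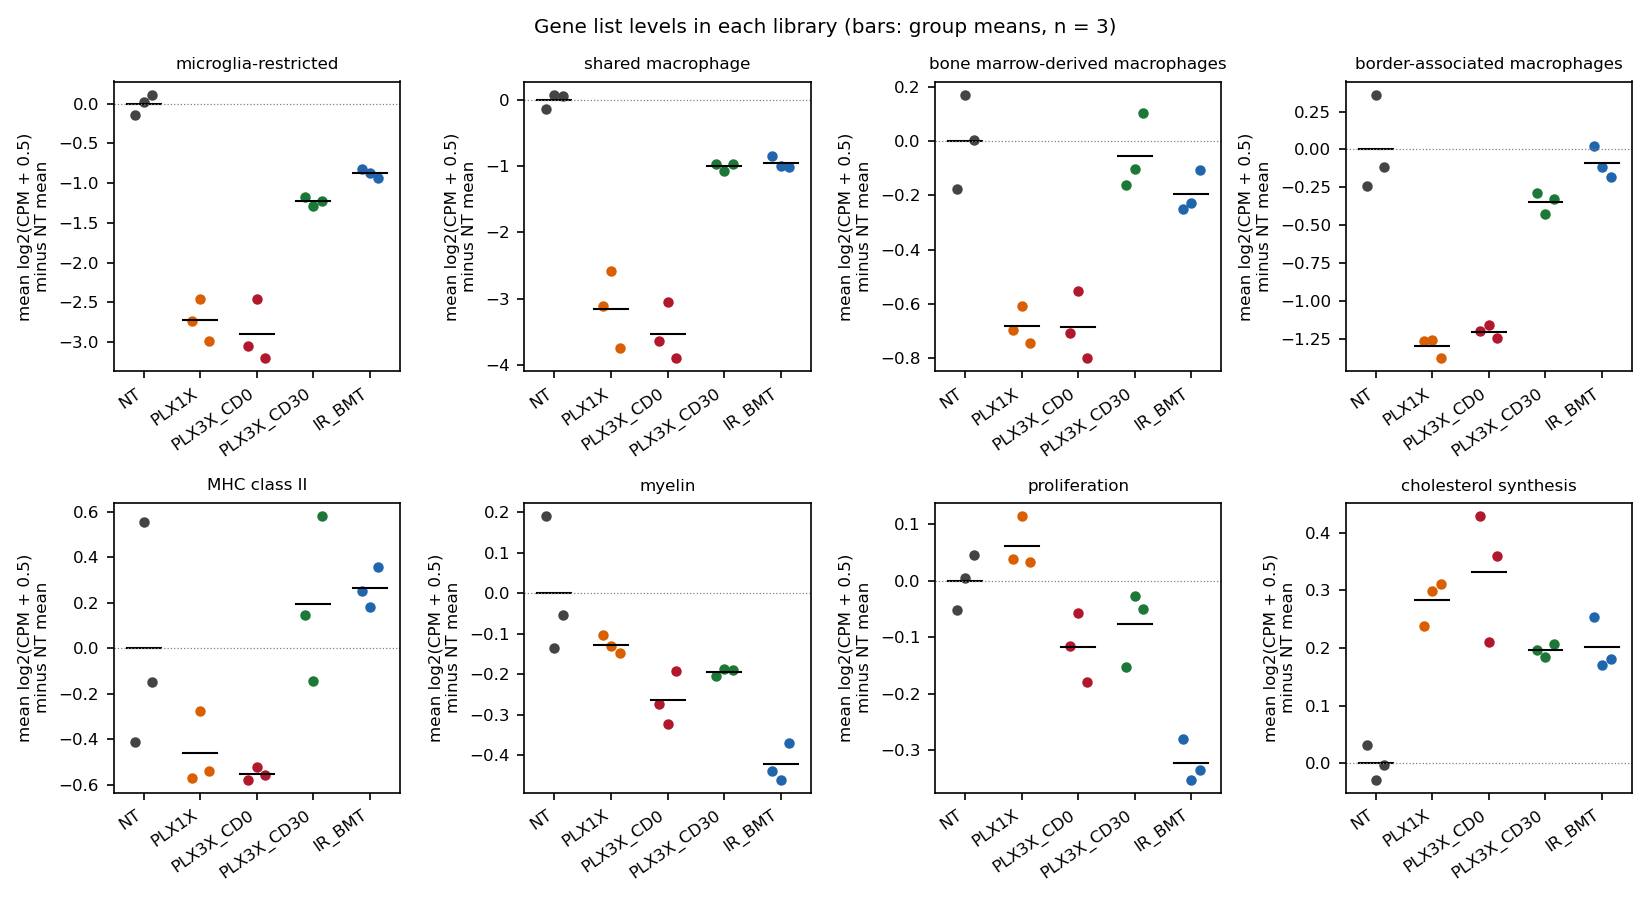
Level of 8 gene lists (panels) in each of the 15 libraries, by group, as the mean over list members of log2(CPM + 0.5) minus its mean in NT; points are libraries, and bars are group means. The microglia-restricted list averaged -2.72 in PLX1X, -2.90 in PLX3X_CD0, -1.23 in PLX3X_CD30 and -0.88 in IR_BMT.

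Macrophage transcripts were higher in IR_BMT than in PLX3X_CD0. Fcrls, an Fc receptor-like gene of microglia (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), was at 17.9 ± 1.07 against 0.492 ± 0.302 CPM, a log2 fold change of 5.19 ± 0.31 (adjusted p = 3.83e-07). All 17 shared macrophage genes rose (median 3.38), with 11 of 13 microglia-restricted genes. Of the MHC class II genes 4 of 8 rose (H2-Eb1, Cd74, H2-Ab1 and H2-Aa) and 5 adjusted over the list alone, adding H2-DMb1. H2-Eb1 changed by 1.43 ± 0.34 (adjusted p = 0.00543). Endothelial genes were lower, 6 of 12 (7 adjusted over the list alone), with Slco1a4 at -0.54 ± 0.07 (adjusted p = 0.371 for the list with an estimated correlation). The striatal list, a sign of dissection, was called lower too, with 2 of 9 members (Drd1 and Tac1) and 5 adjusted over the list alone, adding Ppp1r1b, Rgs9 and Penk (median -0.54, adjusted p = 0.00108, and adjusted p = 0.468 with an estimated correlation). Drd1 did not pass without PLX3X_CD0 replicate 3, IR_BMT replicate 1 or IR_BMT replicate 2, with the length and GC offset, or in a fit on these 6 libraries alone (adjusted p from 1.73e-25 to 0.102 over all alternatives), and Tac1 did not pass without PLX3X_CD0 replicate 2, PLX3X_CD0 replicate 3, IR_BMT replicate 1 or IR_BMT replicate 2, with the length and GC offset, or in a fit on these 6 libraries alone (adjusted p from 5.64e-29 to 0.143 over all alternatives).

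The microglia-restricted, shared and border-associated lists held with an estimated correlation (adjusted p = 0.00504, 0.0128 and 0.0128). The bone marrow-derived list was called, with 7 of 12 members past edgeR, but not in all alternatives (adjusted p from 5.13e-05 to 0.202 with camera). With an estimated correlation, adjusted p = 0.371 for the MHC class II list. Immediate early genes were higher, 6 of 12 over all genes and 9 adjusted over the list alone, with Ier2 at 0.79 ± 0.16 and the list at adjusted p = 0.371 with an estimated correlation. Of the astrocyte markers 6 of 13 rose, with Sox9 at 0.47 ± 0.08 (adjusted p = 0.202 with an estimated correlation). The precursor transcription factors Olig1 and Olig2 rose by 0.47 ± 0.07 and 0.67 ± 0.10, and 5 of 9 genes of the precursor list passed edgeR, though the list was not called. Ier2 did not pass with the length and GC offset (adjusted p from 7.96e-14 to 0.0687 over all alternatives), and Olig1 did not pass with the length and GC offset (adjusted p from 3.04e-09 to 0.144 over all alternatives). In total 4687 genes passed, 2195 higher and 2492 lower, and 2114 with the length and GC offset, 1193 higher and 921 lower, the log2 fold change following GC content across genes with a Spearman coefficient of 0.625. The count was 3029 without IR_BMT replicate 2.

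Between IR_BMT and PLX3X_CD30, 2 of 13 microglia-restricted genes passed edgeR, against 4 with DESeq2. Crybb1 was at 3.17 ± 0.477 against 1.00 ± 0.352 CPM, a log2 fold change of 1.65 ± 0.25 (adjusted p = 0.000295), and Fcrls at 17.9 ± 1.07 against 8.73 ± 1.73 CPM, a change of 1.04 ± 0.23 (adjusted p = 0.00852). The other 11 tested microglia-restricted genes did not pass edgeR, P2ry12 at 13.3 ± 1.43 against 11.9 ± 1.38 CPM. In the edgeR fit over all libraries, none of the shared macrophage, bone marrow-derived or MHC class II genes passed, with 0 at an unadjusted p under 0.05 and 0 past DESeq2 in the shared list, 0 and 0 in the bone marrow-derived list and 0 and 0 in the MHC class II list. That fit takes the spread of a gene from all 15 libraries. The log2 level of the shared list had an SD of 0.59 in PLX1X and 0.43 in PLX3X_CD0, against 0.06 in PLX3X_CD30 and 0.09 in IR_BMT. The lack of calls thus does not show that the 2 groups were alike in shared macrophage genes. Csf1r was at 47.5 ± 1.17 against 55.04 ± 1.10 CPM (adjusted p = 0.743), but a fit on these 6 libraries alone called it lower (log2 fold change -0.22, adjusted p = 0.00826, from 0.00826 to 0.837 over all alternatives). Ms4a7 was at 0.491 ± 0.194 against 0.594 ± 0.443 CPM, a log2 fold change of -0.28 ± 0.58 that did not pass and was 0.47 without PLX3X_CD30 replicate 3.

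The microglia-restricted list had adjusted p = 0.0477 and adjusted p = 0.840 with an estimated correlation. This list did not pass without PLX3X_CD30 replicate 2, PLX3X_CD30 replicate 3, IR_BMT replicate 1 or IR_BMT replicate 2 or with a stricter filter (adjusted p from 0.00303 to 0.840 over all alternatives). Of the myelin genes 8 of 14 fell, with Mal at -0.52 ± 0.08 (adjusted p = 0.830 with an estimated correlation). The oligodendrocyte precursor list was called higher, with 4 of 9 members past edgeR, but not in all alternatives (adjusted p from 0.00238 to 0.840 with camera). Of the endothelial genes 7 of 12 fell (9 adjusted over the list alone), with Slco1a4 at -0.63 ± 0.07 (adjusted p = 0.728 with an estimated correlation). The striatal list, a sign of dissection, was called lower as well (median -0.45, adjusted p = 0.0104, and adjusted p = 0.840 with an estimated correlation), with none of 9 members past edgeR, with 3 at an unadjusted p under 0.05 and 2 past DESeq2. It did not pass without PLX3X_CD30 replicate 2, IR_BMT replicate 1 or IR_BMT replicate 2 (adjusted p from 5.28e-08 to 0.840 over all alternatives). Top2a was at 0.665 ± 0.101 against 1.82 ± 0.286 CPM (adjusted p = 0.00172), 3 of 24 proliferation genes (Top2a, Cenpf and Mki67) fell, and the list was not called (adjusted p = 0.0749). Bbc3, a target of p53, rose by 0.87 ± 0.16. In total 3597 genes passed, 1662 higher and 1935 lower, but 1178 with the length and GC offset, the log2 fold change following GC content across genes with a Spearman coefficient of 0.645. The count was 2053 without PLX3X_CD30 replicate 2, 1975 without IR_BMT replicate 2 and 2123 without IR_BMT replicate 3.

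**Figure D3:**
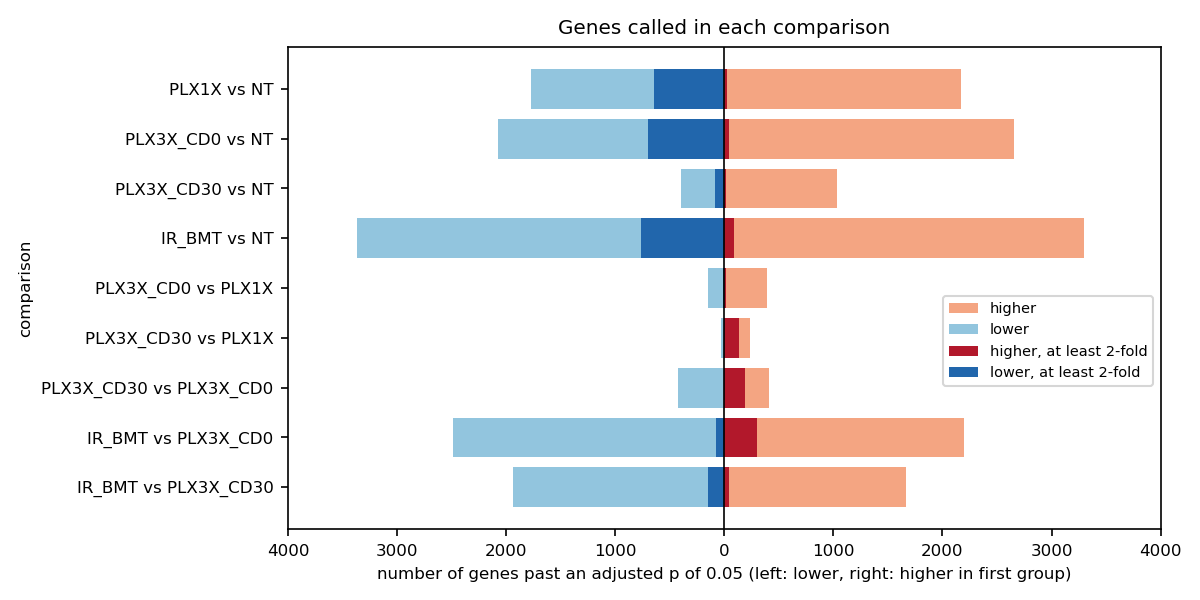
Number of genes past an adjusted p of 0.05 in each of the 9 comparisons, higher in the first group to the right of 0 and lower to the left, with changes of at least 2-fold in the darker colour. IR_BMT vs NT had 6658 such genes and PLX3X_CD30 vs PLX1X 263.

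Libraries also differed in measures of RNA content. The mitochondrial share of counts was 0.727 ± 0.0817% in NT, 0.497 ± 0.0214% in PLX1X, 0.445 ± 0.0323% in PLX3X_CD0, 0.506 ± 0.0198% in PLX3X_CD30 and 0.382 ± 0.0302% in IR_BMT. The share was highest in NT, and the labels name no batch. Changes that all treated groups share against NT thus cannot be told from another handling of the NT libraries. NT replicate 1 held the fewest counts and the largest share of processed pseudogenes, 0.967%, against 0.589% and 0.547% in the other NT libraries. Without it, 3898 genes passed in PLX1X vs NT, 3979 in PLX3X_CD0 vs NT, 1194 in PLX3X_CD30 vs NT and 5904 in IR_BMT vs NT.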

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

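The test with the length and GC offset was chosen after seeing the data, and the other alternatives were planned. RLE factors and the stricter filter left all 20 counts of genes, lists and overlaps within 1.5 times the reported value. Of 103 single-gene results, 73 kept their direction and their side of the threshold in all alternatives that gave a value and 100 kept their direction; of 95 list calls, 18 and 93 did. Leaving out single libraries ended a call in 50 of 618 refits of single genes and 64 of 570 of lists, as fewer samples can, and 2 more list calls ended with the direction turned. The stricter filter removed some of the low genes named, which then had no value.

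A fit on the 6 libraries compared called 2143 genes in PLX1X vs NT, 2601 in PLX3X_CD0 vs NT and 359 in PLX3X_CD30 vs NT, but 814 in PLX3X_CD30 vs PLX1X, and its overlaps held 1384 (PLX1X and PLX3X_CD0) and 320 (PLX3X_CD30 and IR_BMT). These fits estimate the spread from fewer samples, and the prior degrees of freedom were 14.4 in PLX3X_CD30 vs PLX1X and 6.15 in PLX1X vs NT, against 8.71 over all libraries. The spread also differed between groups. Pairs of NT replicates had a chi-square per degree of freedom of 16.8 to 27.1 and those of PLX3X_CD0 of 16.2 to 27.1. Those of PLX1X, PLX3X_CD30 and IR_BMT had 5.91 to 10.5, 3.91 to 7.85 and 5.01 to 12.7. The fit over all libraries takes 1 spread per gene, so it may understate the spread of NT and call too many genes against NT. Without the filter on low counts, the median of the prior degrees of freedom over genes was infinite, so that the own spread of such genes no longer entered their tests. PLX3X_CD0 vs PLX1X then had 1186 calls, PLX3X_CD30 vs PLX1X 696 and PLX3X_CD30 vs PLX3X_CD0 1395, and 11 lists were called in IR_BMT vs NT and 10 in IR_BMT vs PLX3X_CD30. DESeq2 called 1066 genes in PLX3X_CD0 vs PLX1X and 553 in PLX3X_CD30 vs PLX1X, and 11 lists in IR_BMT vs NT and 11 in IR_BMT vs PLX3X_CD30; the cause was not tested. With the length and GC offset, 328 genes passed in PLX3X_CD0 vs PLX1X, 2114 in IR_BMT vs PLX3X_CD0 and 1178 in IR_BMT vs PLX3X_CD30. It moved the share of higher calls by over 10 percentage points in PLX3X_CD30 vs NT (1032 higher and 400 lower against 873 and 560), PLX3X_CD0 vs PLX1X (390 higher and 146 lower against 149 and 179) and PLX3X_CD30 vs PLX3X_CD0 (407 higher and 421 lower against 484 and 227), and by less, but past an even split, in PLX1X vs NT (2171 higher and 1768 lower against 1943 and 1973), PLX3X_CD0 vs NT (2657 higher and 2075 lower against 2065 and 2244) and IR_BMT vs PLX3X_CD0 (2195 higher and 2492 lower against 1193 and 921). Over all alternatives but the block, the percentage of calls that were higher ran over 49.6 to 59.3, 47.9 to 59.9, 54.4 to 78.0, 45.7 to 53.1, 45.4 to 79.2, 66.2 to 98.4, 39.9 to 68.1, 42.7 to 56.4 and 39.7 to 52.4 in the order of the comparisons given next. With an estimated correlation, 3 lists were called in PLX1X vs NT, 3 in PLX3X_CD0 vs NT, 1 in PLX3X_CD30 vs NT, 0 in IR_BMT vs NT, 0 in PLX3X_CD0 vs PLX1X, 4 in PLX3X_CD30 vs PLX1X, 4 in PLX3X_CD30 vs PLX3X_CD0, 3 in IR_BMT vs PLX3X_CD0 and 0 in IR_BMT vs PLX3X_CD30. With both changes at least 2-fold the overlaps held 428 and 54 genes, fewer by construction.

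Leaving out each library in turn, the genes called ranged over 2696 to 3932 in PLX1X vs NT, 3499 to 5114 in PLX3X_CD0 vs NT, 608 to 1714 in PLX3X_CD30 vs NT, 5097 to 6827 in IR_BMT vs NT, 150 to 289 in PLX3X_CD0 vs PLX1X, 125 to 188 in PLX3X_CD30 vs PLX1X, 384 to 563 in PLX3X_CD30 vs PLX3X_CD0, 3029 to 4441 in IR_BMT vs PLX3X_CD0 and 1975 to 3526 in IR_BMT vs PLX3X_CD30. In the same order, the lists called ranged over 12 to 15, 11 to 16, 14 to 17, 7 to 11, 6 to 10, 11 to 13, 10 to 13, 11 to 15 and 2 to 7. The overlaps ranged over 2077 to 2874 (PLX1X and PLX3X_CD0) and 524 to 1441 (PLX3X_CD30 and IR_BMT). Without single libraries, the log2 fold change of Ms4a7, which passed in none of these comparisons, ran from -0.66 without PLX3X_CD30 replicate 3 to 0.49 without PLX3X_CD30 replicate 2 in PLX3X_CD30 vs NT, from -0.51 without IR_BMT replicate 1 to 0.0570 without IR_BMT replicate 2 in IR_BMT vs NT and from -0.68 without PLX3X_CD30 replicate 2 to 0.47 without PLX3X_CD30 replicate 3 in IR_BMT vs PLX3X_CD30. With the length and GC offset it was 0.000217 in IR_BMT vs NT. Among called lists, the median of the thalamic list in PLX3X_CD30 vs NT ran from -0.80 without NT replicate 2 to 0.0393 without NT replicate 1, and that of the choroid plexus list in PLX3X_CD0 vs PLX1X from -0.17 without PLX3X_CD0 replicate 1 to 3.38 without PLX3X_CD0 replicate 3; the cause was not tested.

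The labels give every group the replicate numbers 1 to 3, but the numbers did not pair the samples: deviations of same-numbered libraries correlated with a median of 0.00175 (-0.0896 to 0.226), 4 of 30 above 0.1. With the number as a replicate block, 3833, 4575, 1241, 6517, 454, 243, 754, 4517 and 3422 genes were called in the same order of comparisons, each within 1.5 times the reported count. Ms4a7 in PLX3X_CD30 vs NT turned to -0.0729 under the block. It left Rora in PLX3X_CD0 vs NT at adjusted p = 0.0525 (7.06e-07 to 0.135 over all alternatives), Tcf7l2 in IR_BMT vs NT at 0.0772 (6.31e-27 to 0.214), Tac1 in IR_BMT vs PLX3X_CD0 at 0.0572 (5.64e-29 to 0.143), Cd74 in PLX3X_CD30 vs PLX3X_CD0 at 0.0670 (4.04e-37 to 0.139), and in IR_BMT vs PLX3X_CD30 the microglia-restricted and precursor lists at 0.0555 and 0.0555 (0.00303 to 0.840 and 0.00238 to 0.840). The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05: in each comparison 1 split, the real one, called as many genes as reported, and the highest of the others called 9, 1, 0, 0, 12, 0, 0, 0 and 1 in the same order, against 3939, 4732, 1432, 6658, 536, 263, 828, 4687 and 3597 for the real splits. Each other split mixes libraries of both groups, so a difference from any source widens the spread and lowers the calls. The low counts there thus do not bear on the source of the calls.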

Other observations

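Apart from the comparison of phases in clock genes, the glucocorticoid genes and the splits of libraries, the tests below were chosen after the results were seen.

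Some genes rose against NT in each treated group. These comparisons share the same NT libraries, so their results are not independent, and a low level in NT would raise a gene in each. Il34, a second ligand of Csf1r, rose by 0.38 ± 0.08 in PLX1X, 0.32 ± 0.08 in PLX3X_CD0, 0.31 ± 0.08 in PLX3X_CD30 and 0.52 ± 0.08 in IR_BMT (log2 fold change ± SE, n = 3). In PLX3X_CD0, Il34 did not pass in a fit on these 6 libraries alone (adjusted p from 0.000148 to 0.0693 over all alternatives), and in PLX3X_CD30 it did not pass without PLX3X_CD30 replicate 1, PLX3X_CD30 replicate 2 or PLX3X_CD30 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 0.00196 to 0.149 over all alternatives). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 0.57 ± 0.10, 0.55 ± 0.10, 0.62 ± 0.10 and 0.56 ± 0.10 in the same order, and the complement gene C4b by 1.12 ± 0.23 in PLX3X_CD0, while the reactive astrocyte list was called in none of the 9 comparisons (smallest adjusted p = 0.0645 with camera). Sesn2, a stress-induced target of p53, rose by 0.35 ± 0.08 in PLX3X_CD0 and 0.44 ± 0.08 in IR_BMT. In IR_BMT Sesn2 did not pass with the length and GC offset (adjusted p from 5.78e-06 to 0.106 over all alternatives), and the neurogenesis gene Sox11 changed by -0.86 ± 0.13.

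Genes that mark other regions and tissues varied too. The hypothalamic hormone gene Oxt changed by -6.40 ± 1.71 in PLX3X_CD0 vs NT and -3.08 without NT replicate 1, with NT libraries at 13.6, 0.446 and 0.479 CPM. Prkcd, listed for thalamic neurons, changed by -2.11 ± 0.61 there and -1.19 without NT replicate 1. Oxt did not pass without PLX3X_CD0 replicate 1, PLX3X_CD0 replicate 2 or PLX3X_CD0 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 3.99e-41 to 0.133 over all alternatives), and Prkcd did not pass without NT replicate 1, PLX3X_CD0 replicate 1, PLX3X_CD0 replicate 2 or PLX3X_CD0 replicate 3 or in a fit on these 6 libraries alone (adjusted p from 2.87e-89 to 0.131 over all alternatives). The erythrocyte list was called lower in PLX1X vs NT (adjusted p = 0.0344, and adjusted p = 0.553 with an estimated correlation), with none of 6 members past the edgeR test, with 2 at an unadjusted p under 0.05 and 0 past DESeq2. It did not pass without NT replicate 2, PLX1X replicate 2 or PLX1X replicate 3, with a stricter filter, or with the length and GC offset (adjusted p from 6.34e-05 to 0.553 over all alternatives). It was also called lower in PLX3X_CD30 vs NT (adjusted p = 0.0161, and adjusted p = 0.489 with an estimated correlation), with none of 6 members past the edgeR test, with 1 at an unadjusted p under 0.05 and 0 past DESeq2. There it did not pass without NT replicate 2 or with a stricter filter (adjusted p from 0.000329 to 0.489 over all alternatives). The lists for neurogenesis, p53 targets, lymphocytes, neutrophils, pericytes, meningeal fibroblasts, ependyma and hypothalamic neurons were called in none of the 9 comparisons, with smallest adjusted p values of 0.130, 0.154, 0.102, 0.421, 0.137, 0.344, 0.0509 and 0.130.

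Macrophage gene groups stood at different shares of their NT level in PLX3X_CD30, and IR_BMT was tested in the same way; fewer cells of an unchanged kind, or blood left in the tissue, could be the source of such a difference. With the PLX3X_CD0 mean as 0% and the NT mean as 100%, the median shared macrophage gene stood at 46.8% (SD 2.93) in PLX3X_CD30. The median microglia-restricted gene stood at 29.6% (SD 0.869). This gap of 17.2 points lay between 14.9 and 19.6 in its libraries, and was 14.3 with PLX1X as the low level. In NT it was 0.963 to 6.08, but the scale sets each gene's NT mean to 100%, so a small gap there was fixed in advance. The NT range thus cannot show how far unchanged cells would scatter midway on the scale. Single genes of both sets overlapped, the shared from 30.6% (Csf1r) to 54.2% (C1qc) and the restricted from -84.2% (Sall3) to 62.5% (Olfml3). The shared median was higher in each PLX3X_CD30 library. Fewer cells of an unchanged kind would put both sets at the same share. For the medians of these sets, the gap in PLX3X_CD30 thus argues against fewer unchanged cells as the whole cause. In IR_BMT the gap was 4.69 points (1.81 to 8.83) and -1.14 with PLX1X as the low level, which decides nothing. This gap was tested only after a first one, between the bone marrow-derived plus MHC class II genes and the microglia-restricted genes, had not decided: that gap was 87.7 points in PLX3X_CD30 (SD 66.2) and 69.8 in IR_BMT (SD 11.1), but the 3 NT libraries alone ran over -24.9, 83.9 and -40.3, so the test was set aside as void, although the bound first written would have read the PLX3X_CD30 gap, under 2 SD, as what fewer unchanged cells give. For blood, the 11 erythrocyte and granulocyte genes tested had a median log2 fold change against NT of -0.50 in PLX3X_CD30 (5 higher, all of them granulocyte genes, 6 lower) and -0.20 in IR_BMT (4 higher, again granulocyte genes, 7 lower), and all 6 erythrocyte genes lay below NT without passing, at -2.31 to -0.50 and -1.12 to -0.20, which goes against more blood than in NT, but the erythrocyte levels of the PLX3X_CD30 libraries (-0.81 to -0.63) and IR_BMT libraries (-1.14 to -0.35) did not stand apart from those of PLX3X_CD0 (-1.10 to -0.07), the low level of the scale, so blood was left open although the bound first written would have excluded it in both groups. The treatments themselves, with another mix of macrophages or another state of the same ones, remain as untested explanations, and the markers alone cannot tell resident from engrafted cells.

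Several genes of the circadian clock differed between PLX3X_CD0 and PLX1X, among them Ciart (-1.47 ± 0.14), Per2 (-0.94 ± 0.13), Dbp (-0.76 ± 0.15) and, the other way, Arntl (0.51 ± 0.09). Collection at another time of day, or a glucocorticoid response, could give this, and for each a test was written before its genes were looked at. The median log2 fold change of Npas2, Clock, Cry1 and Nfil3 minus that of Per3, Nr1d1 and Hlf, which peak in the opposite phase, was 0.54. This lay above the 0.2 set for a shift of phase. Its SE of 0.07 is that of a difference of means of independent genes and leaves out the spread between genes, so it understates the uncertainty. Npas2 (0.43 ± 0.07), Clock (0.27 ± 0.07) and Nr1d1 (-0.38 ± 0.07) passed the test, and Cry1 (-0.37 ± 0.11) went the other way without passing. The 7 glucocorticoid-induced genes had a median of 0.0183 (SE 0.07, computed in the same way), with Errfi1 alone past the test (-0.36 ± 0.07), which decides nothing. The labels give no time of collection, and an effect of the treatment on the clock remains untested.

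Most calls in the IR_BMT comparisons changed less than 2-fold and followed GC content across genes, so transcript length and GC trends between libraries, or the shallow NT replicate 1, could lie behind them. With the length and GC offset, 21.8% of the calls under 2-fold in IR_BMT vs PLX3X_CD30 passed in the same direction, under the 50% set for this explanation. In IR_BMT vs NT 54.6% did, between the 50% and 80% set, which leaves it open. Outside these tests, 28.7% did in IR_BMT vs PLX3X_CD0 and 42.0% in PLX3X_CD0 vs PLX1X. Larger calls were lost too, with 81 of 191 of at least 2-fold kept in IR_BMT vs PLX3X_CD30 and 590 of 852 in IR_BMT vs NT. Without NT replicate 1, 81.0% of the calls under 2-fold in IR_BMT vs NT passed in the same direction, which argues against that library as the whole cause. The offset also removes any effect of the treatment that runs with length or GC content, so a biological difference remains open.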
